A study of Oryza sativa with 12 samples.

How the data were processed

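Leaves of rice variety Pusa Basmati-1 were sequenced in 12 libraries, 2 in each of 6 groups: a WT, an OE and a KO group for OsPIP2-1 and the same for OsPIP2-7. Groups and replicate numbers were taken from the sample titles. The deposited count table holds raw read counts per gene for all libraries, and per the file headers it was made with featureCounts 1.4.0 on the IRGSP-1.0 genome with the Ensembl Plants annotation, release 52. Per the file headers, reads were counted on the reverse strand, reads with several alignments were counted at each place, and reads overlapping several genes were left out. Genes with near-identical copies, such as PIP2 genes, metallothioneins and the OsRLCK144 loci, can therefore share reads, and their counts are uncertain. Trim Galore, HISAT2 and Cufflinks are named in the submitters' processing notes without versions. The deposited comparison tables give log2 fold changes between groups as the authors computed them with Cuffdiff 2.2.1, per the submitters' processing notes. The p-values and q-values in these deposited tables are also the authors' own, and the tables were used only for gene names and for the values credited to them. Gene coordinates are those of the count table, on IRGSP-1.0. Of 37849 nuclear genes 9826 had a name in the authors' tables, the other genes are given by locus, and a list of several names was shortened to the first.

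The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries were scaled by TMM, and groups were compared by the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each experiment was fitted on its own 6 libraries, so that its groups share an estimate of the spread. The comparison of the WT pairs and the tests of the difference between experiments were fitted on all 12 libraries. Levels are means of TMM-scaled CPM (cpm in edgeR) with the SD over 2 libraries. Each SE of a log2 change was back-calculated as its absolute value over the square root of the quasi-likelihood F, and is approximate. The replicates of a group were compared before averaging: their counts differed by more than sampling noise in each group (chi-square per degree of freedom 2.50 to 7.71), so none was taken as a library deposited again. At the smallest library total, 24636211 counts, 1 CPM before TMM scaling stands for 24.6 counts. Folds against a group at 0 are lower bounds from a floor of 3 counts over the group, and groups with 1 to 3 counts have a ratio with a 95% exact (Clopper-Pearson) interval. Both cover counting error only, since reads were not tagged by molecule.

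Groups, comparisons, tests, alternatives and the rule for named genes were chosen before the data were examined. That rule took, for each comparison with WT, both targets and any other PIP gene past the threshold. It also took the 8 largest rises and the 8 largest falls among named genes past the threshold with a mean of at least 5 CPM whose libraries did not overlap between groups. It then took up to 4 called members, by smallest p, of each fixed gene list that passed its test or had at least 3 called members, and up to 4 genes each way called in opposite directions in OE and KO. The 6 fixed lists were PIP aquaporins, other aquaporins, circadian clock, flowering, floral and meristem markers (another tissue), and the cellulose synthases of secondary walls (vascular tissue). They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks only whether a list's own genes move one way. Adjustment ran over the 6 lists in 4 comparisons together. Further lists had been planned from gene descriptions, which the sources used here did not give. In their place 20 lists were defined from gene names after the data had been opened, and they were adjusted apart from the fixed lists.

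The alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, a fit of all 12 libraries, a fit of only the 4 libraries compared, the replicate number as a block, each library left out in turn, nuclear genes only, and all 4 WT libraries as the reference. Calls against both WT pairs, replicates summed within groups, and genes outside certain chromosome segments were added after seeing the data. The procedure was tested on simulated counts drawn from the real means, with 63 to 67 scored genes changed at each fold. For PIP2-1 KO against WT (23009 genes) edgeR recovered 59.7%, 78.8% and 93.9% of genes changed by 1.5-fold, 2-fold and 4-fold, and 6.67% of its calls were false. The shares were 69.8%, 80.6% and 95.3% for PIP2-7 KO against WT (23026 genes, 3.64% false), and 64.1%, 79.7% and 95.3% for the WT pairs (23742 genes, 4.97% false). The simulated counts held only the spread between libraries of a group. These false shares therefore do not cover differences between groups of one genotype, such as the 13907 genes called between the real WT pairs.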

Results

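Transcript levels were measured by RNA sequencing in leaves of rice (Oryza sativa, indica variety Pusa Basmati-1), an aromatic long-grain cultivar. The study addressed OsPIP2-1 and OsPIP2-7, members of the PIP family of aquaporins, the water channels of the plasma membrane. For each gene there was an overexpression line (OE), in which a tagged copy was driven by the maize ubiquitin promoter, a CRISPR-Cas9 knockout line (KO) free of T-DNA, and its own wild type (WT). The 12 libraries therefore form 6 groups of 2, and each target gene has an experiment of 6 libraries. Library totals ran from 24636211 to 40666127 counts over 38978 annotated genes, and OsMT3a, a metallothionein gene, was the most abundant in each library, with at least 4.15% of counts. The labels do not say that the 2 libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical. That spread was small: the biological coefficient of variation within groups was 2.61% to 4.83%, against 40.8% between the summed WT libraries of one experiment and those of the other.

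The transcripts of both targets were examined first, in every group. OsPIP2-1 (Os07g0448800, chromosome 7, 15406442 to 15409748, plus strand, 3 exons, IRGSP-1.0) stood at 132 ± 0.687 CPM (counts scaled by library size and TMM; SD, n = 2) in its WT and at 1901 ± 36.6 CPM (SD, n = 2) in its OE line, a log2 change of 3.85 (SE 0.04). The edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 5.04e-39 for that rise. In the PIP2-1 KO it stood at 138 ± 4.55 CPM (SD, n = 2), a log2 difference of 0.06 from WT that did not pass the test (edgeR, adjusted p = 0.192). Without replicate 1 of the PIP2-1 KO the difference was 0.10 and passed narrowly (edgeR, adjusted p = 0.0402, against up to 0.889 under the other alternatives), so the knocked-out gene was not lower in its own knockout in either case. A CRISPR edit can leave the transcript level as it was, and the counts do not show the edited bases, so the level does not test that label. OsPIP2-7 (Os09g0541000, chromosome 9, 21310132 to 21311479, plus strand, 2 exons) rose from 687 ± 6.04 to 1708 ± 73.6 CPM (SD, n = 2) in its OE line, by 1.29 on the log2 scale (SE 0.03). The same gene changed by -2.13 on the log2 scale in its KO, to 158 ± 3.26 CPM (SD, n = 2), and edgeR gave adjusted p = 5.52e-36 for the rise and 6.10e-43 for the fall. OsPIP2-7 was also higher in the PIP2-1 KO, at 962 ± 38.5 against 337 ± 1.85 CPM (SD, n = 2), while its levels in the WT pairs themselves differed by 1.03 on the log2 scale. Against the other WT pair OsPIP2-7 stood at 2.34 in its OE line, -1.09 in its KO and 0.49 in the PIP2-1 KO. The authors' deposited table gave log2 changes of 1.91 and 0.63 for OsPIP2-1 in OE and KO, the second not significant there, and the authors' deposited table for the other experiment gave 0.64 and -1.83 for OsPIP2-7.

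**Figure D1:**
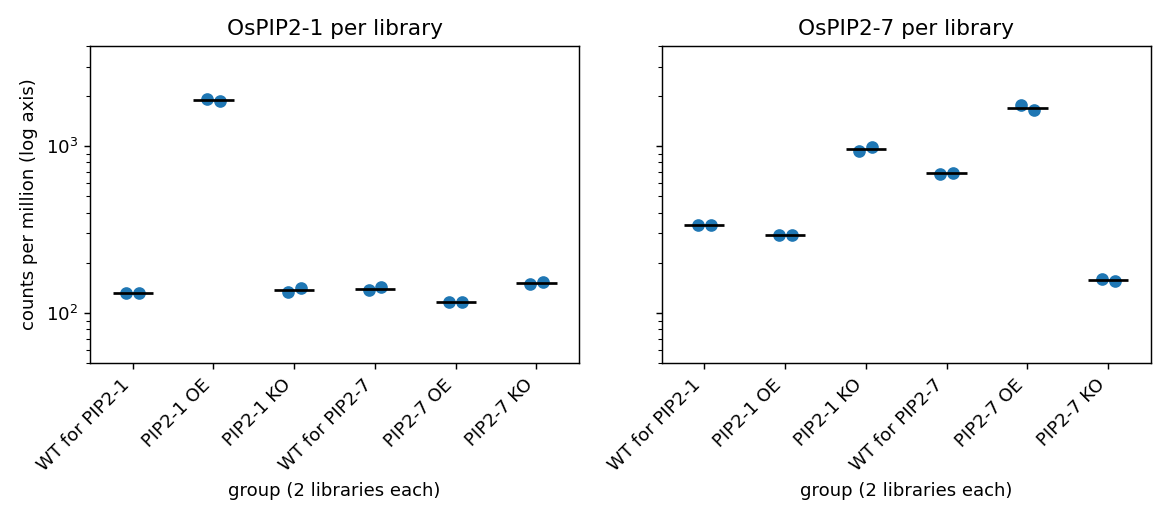
Normalized level of OsPIP2-1 (left) and OsPIP2-7 (right) in each of the 12 libraries, in CPM on a log axis, with a line at the mean of each group of 2. OsPIP2-1 stands apart in its own OE line at 1901 CPM and lies near 138 CPM in its KO, and OsPIP2-7 lies at 1708 CPM in its OE line and at 158 CPM in its KO.

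The wild types of the experiments were compared to give the background against which the other comparisons are read, since variety, tissue and age were the same per the labels. Of 24556 genes tested, 13907 differed between the WT pairs by the edgeR test, 6901 higher and 7006 lower in the WT of the PIP2-7 experiment, and 3899 of them by at least 2-fold. OsRFT1 and OsHd3a, which encode mobile flowering signals, stood at -4.71 and -5.11 on the log2 scale in that WT relative to the other, and the floral-transition gene OsMADS14 at -5.74. The stay-green gene SGR, which acts in chlorophyll breakdown, stood at -4.58 there (SE 0.07), while PsbO, a subunit of photosystem II, was higher by 1.61 (SE 0.03). Among the 6 gene lists fixed before the data were examined, flowering genes were lower in the PIP2-7 WT (3 up and 6 down of 11, and 3 up and 6 down adjusted over the list alone; camera, adjusted p = 9.9e-08, and adjusted p = 0.0062 with an estimated correlation). PIP genes (6 up and 3 down of 10, the same counts adjusted over the list alone) and other aquaporins (7 up and 3 down of 13, the same counts adjusted over the list alone) passed camera with adjusted p = 0.023 and 0.0064, against adjusted p = 0.28 and 0.11 with an estimated correlation. Clock genes (3 up and 4 down of 8), floral markers (2 up and 1 down of 5) and secondary wall cellulose synthases (0 up and 1 down of 3), with the same counts adjusted over the list alone, did not pass (camera, lowest adjusted p = 0.97). The labels name no day or batch for either experiment, so each OE and KO line was tested against its own WT, and for named genes the value against the other WT pair is given where the call turned or was lost.

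In leaves overexpressing OsPIP2-1, 10355 of 23487 genes differed from WT, 5452 higher and 4903 lower, and 2208 of these by at least 2-fold (edgeR quasi-likelihood test). The largest rises included OsHXK1, a hexokinase gene (Os07g0446800, chromosome 7, 15293180 to 15294805), which stood at 12.1 ± 0.492 CPM (SD, n = 2) and at 0 in both WT libraries, so that it was at least 266-fold higher by a floor of 3 counts over the WT pair. OsRCI2-9 (Os06g0651900) rose by 8.38 on the log2 scale (SE 0.25). The non-coding phosphate-starvation RNAs OsIPS2 and OsIPS1 rose by 6.56 (SE 0.16) and 6.22 (SE 0.27), the nitrate-response repressor NIGT1 by 5.74 (SE 0.17), the purple acid phosphatase OsPAP23 by 5.05 (SE 0.16) and TOND1 by 4.85 (SE 0.13). VLN4, which encodes an actin-binding villin, rose by 6.08 (SE 0.24). The falls were led by the asparaginase gene OsASNase2 (Os04g0650700), from 1378 ± 40.9 to 129 ± 1.18 CPM (SD, n = 2), a log2 change of -3.42 (SE 0.04). Log2 changes were -3.16 for XBOS36, -2.88 for the phosphate transporter gene OsSPX-MFS1 and -2.43 for the nitrate transporter gene NRT2.4. The metallothionein genes OsMT1g, MTI4C, OsMT1f and OsMT1c of chromosome 12 changed by -3.09, -2.93, -2.86 and -2.79. All 8 rises also passed against the other WT pair, where VLN4 kept its size (log2 6.11). OsRCI2-9, OsIPS2 and OsIPS1 shrank there to 1.97, 1.30 and 2.25, and NIGT1, OsPAP23 and TOND1 to 1.79, 1.41 and 2.65. Of the 8 falls, 6 passed in the same direction against that pair, while XBOS36 passed in the opposite one (0.17) and OsASNase2 did not pass (0.058). Those 6 were smaller there, with OsSPX-MFS1 at -1.13, NRT2.4 at -0.84, and OsMT1g, MTI4C, OsMT1f and OsMT1c at -1.49, -1.57, -1.43 and -1.02. With all 4 WT libraries as the reference OsRCI2-9, OsIPS2, NIGT1 and OsPAP23 (2.95, 2.26, 2.69 and 2.30) did not pass. OsASNase2, XBOS36 and NRT2.4 (-2.55, -2.30 and -1.84) did not either.

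The PIP list rose in this line, with 6 members up and 3 down of 10 tested (7 and 3 adjusted over the list alone), and camera gave adjusted p = 2.7e-12, but adjusted p = 0.26 with an estimated correlation. The list contains the overexpressed gene itself. OsPIP2-3 rose from 6.68 ± 0.603 to 84.9 ± 5.03 CPM (SD, n = 2), by 3.65 on the log2 scale (SE 0.09), and its counts can include reads of OsPIP2-1, since reads with several alignments were counted. OsPIP2-2, OsPIP1-2 and OsPIP1-1 rose by 0.97, 0.50 and 0.48, and OsPIP1-3 by 0.18, while OsPIP2-7 and OsPIP2-6 fell, with log2 changes of -0.20 and -0.18, and OsPIP2-5 fell from 2.55 ± 0.391 to 1.29 ± 0.276 CPM (SD, n = 2). Without replicate 2 of the WT the calls of OsPIP1-3 (0.11) and OsPIP2-5 (-0.82) were lost, and that of OsPIP2-6 was lost without any 1 of the 4 libraries compared (-0.16 to -0.20 for the WT replicates left out in turn) and with DESeq2 (-0.18). OsPIP1-1 and OsPIP2-5 turned against the other WT pair, to -0.50 and 0.87, and OsPIP2-2 did not pass (0.078). Among other aquaporins 4 rose and 4 fell of 13 (the same adjusted over the list alone), with the tonoplast aquaporin genes OsTIP2-2 and OsTIP4-2 at 1.35 and 0.57, OsNIP2-2 at 0.87 and OsTIP1-2 at -0.96, and a median of -0.089 where camera pointed up. OsTIP2-2 and OsTIP4-2 turned against the other WT pair, to -0.48 and -0.31. Of 8 circadian clock genes 0 rose and 4 fell (also adjusted over the list alone), namely OsGI, OsPRR95, OsPRR59 and OsPRR73, at -0.30, -0.21, -0.19 and -0.16. OsPRR59 turned against the other WT pair (0.17), and OsGI and OsPRR95 did not pass (-0.049 and 0.037). Of 11 flowering genes 0 rose and 5 fell (also adjusted over the list alone), with OsRFT1 at -1.80, OsMADS15 at -1.35, OsMADS18 at -0.61 and OsMADS51 at -0.29, although OsRFT1 and OsMADS18 were higher than in the other WT pair, by 2.91 and 0.89, OsMADS15, with 2 counts in that pair, was higher too, and OsMADS51 did not pass (-0.070). Floral and meristem markers (1 up and 1 down of 4, also adjusted over the list alone) and the cellulose synthases of secondary walls (1 up and 0 down of 3, with 0 adjusted over the list alone) gave few calls. None of these last 5 lists passed camera, the lowest adjusted p being 0.0597 for flowering.

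In the PIP2-1 KO line 14666 of 23487 genes differed from WT, 7175 higher and 7491 lower, and 5176 by at least 2-fold (edgeR quasi-likelihood test). The Bowman-Birk protease inhibitor gene RBBI2-1 (Os01g0124000, chromosome 1, 1341368 to 1342277) rose from 0.748 ± 0.229 to 90.4 ± 4.43 CPM (SD, n = 2), by 6.97 on the log2 scale (SE 0.12). OsPR2, a glucanase gene, rose by 6.41 (SE 0.23), the ribonuclease gene RNS4 and the chitinase gene Cht4 (Os04g0493400) by 5.06 each, the ureide permease gene OsUPS1 by 5.01, OsGELP84 by 5.00, OsPR4 by 4.95 and PI21 by 4.86. The falls were led by OsASNase2, from 1378 ± 40.9 to 8.16 ± 0.435 CPM (SD, n = 2), a log2 change of -7.41 (SE 0.05). The ammonium transporter gene AMT3 and the urea transporter gene OsDUR3 changed by -5.24 and -4.63. LOGL9, of the cytokinin-activating LOG family, changed by -5.67, the NAC transcription factor gene ONAC103 by -4.79, SGR by -4.39, and the neighbouring loci Os04g0369000 and Os04g0369066, both named OsRLCK144, by -4.86 and -4.30. Against the other WT pair, 4 of these 8 rises passed in the same direction (RBBI2-1 2.42, OsUPS1 3.93, OsGELP84 3.88, PI21 6.47) and 4 in the opposite one (OsPR2 -0.95, RNS4 -1.40, Cht4 -0.79, OsPR4 -0.69). Of the 8 falls 4 passed in the same direction there but shrank, OsASNase2 to -3.93, LOGL9 to -1.78, ONAC103 to -1.24 and OsDUR3 to -0.95. For these genes the PIP2-7 WT itself stood at -3.48, -3.90, -3.54 and -3.67 relative to the PIP2-1 WT. The OsRLCK144 loci passed in the opposite direction, at 1.26 and 1.27, and AMT3 and SGR did not pass (-0.19 and 0.19). OsPR2, Cht4, OsPR4 and RNS4 (0.046, 0.19, 0.28 and -0.42) did not pass with all 4 WT libraries as the reference. AMT3, SGR and the OsRLCK144 loci (-4.27, -3.43, -3.87 and -3.33) did not either.

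Of 10 PIP genes 6 rose and 3 fell in the PIP2-1 KO (the same adjusted over the list alone), with OsPIP1-3 at -2.51 (SE 0.05) and OsPIP2-7, OsPIP2-2 and OsPIP1-1 up by 1.51, 1.10 and 0.96. OsPIP1-2, OsPIP2-6 and OsPIP2-3 rose by 0.64, 0.61 and 0.29, and OsPIP2-4 and OsPIP2-5 changed by -1.69 and -2.18. The call of OsPIP2-3 was lost without WT replicate 1 (0.22), without KO replicate 1 (0.0064), with DESeq2 and with only the 4 libraries compared (0.30 each). OsPIP1-3 stood at -2.18 against the other WT pair, while OsPIP1-1, OsPIP2-6, OsPIP2-3, OsPIP2-4 and OsPIP2-5 did not pass (-0.028, 0.077, 0.28, -0.43 and -0.31). Other aquaporins (5 up, 2 down of 13), clock genes (2 up, 4 down of 8), flowering genes (2 up, 4 down of 11), floral markers (1 up, 1 down of 4) and secondary wall cellulose synthases (2 up, 0 down of 3) had the same counts adjusted over the list alone. OsTIP2-2, OsTIP4-2 and OsTIP1-1 rose by 1.72, 0.97 and 0.62 and OsTIP1-2 changed by -0.37, but against the other WT pair OsTIP2-2 turned (-0.11) and OsTIP4-2 did not pass (0.092). OsPRR59, OsPRR1 and OsPRR95 changed by -0.63, -0.57 and -0.48 and OsLHY by 0.21, which did not pass against the other WT pair (-0.073). OsMADS15, OsHd3a, OsMADS14 and OsMADS51 changed by -3.19, -1.15, -1.06 and -0.70, although OsMADS14 and OsHd3a were higher than in the other WT pair, by 4.69 and 3.96, and OsMADS15 was higher too. No fixed list passed camera here, the lowest adjusted p being 0.19, and adjusted p = 0.56 with an estimated correlation.

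The OE and KO lines of OsPIP2-1 were then set against each other to ask whether opposite changes of dose gave opposite changes of transcripts. Directly compared, 13036 genes differed, 6733 higher in OE and 6303 higher in KO (edgeR quasi-likelihood test). More genes moved in the same direction against WT than in opposite directions: 3664 were higher and 3379 lower in both, against 748 higher in OE and lower in KO and 452 the other way. Without WT replicate 2 the opposite genes numbered 784, compared with 1200 in all 6 libraries. Independent lists of these sizes would share 1666 and 1564 genes in the same direction and 1739 and 1498 in opposite ones. Both comparisons use the same WT pair, and 10 simulations of unchanged lines against it gave a correlation of log2 changes across genes of 0.506 and a covariance of 0.0238, against an observed correlation of 0.48 and covariance of 0.553. The simulated lines had 0.1 and 0 genes called on average, which left no room for an overlap. The simulations held only the spread between libraries of a group, not a deviation shared by a whole WT pair. Such deviations can be large, since the summed WT libraries of the experiments differed with a coefficient of variation of 40.8%. Part or all of the excess may therefore come from the shared WT, whose libraries were not split between the comparisons. The glycine-rich protein gene GRP stood at 2.36 in OE and -2.77 in KO, and held both directions against the other WT pair (2.01 and -3.12). The low-temperature germination gene qLTG-3-1(t) stood at 2.50 and -2.50, RbohF, an NADPH oxidase gene, at 2.24 and -2.27, and GH2, a lignin-pathway gene, at 2.44 and -2.16. In the other direction, lower in OE and higher in KO, stood OsMFT1 (-1.60 and 2.01), the peroxidase gene prx29 (-1.87 and 1.43), PI21 (-1.25 and 4.86) and the wall-modifying OsXTH6 (-1.17 and 1.27). Against the other WT pair RbohF in KO (-0.41) and PI21 in OE (0.36) did not pass, and GH2 in KO turned (0.55).

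In leaves overexpressing OsPIP2-7, 15857 of 23627 genes differed from WT, 7889 higher and 7968 lower, and 5221 by at least 2-fold (edgeR quasi-likelihood test). The largest rises included OsMADS15 (Os07g0108900, chromosome 7, 471234 to 477655), which stood at a mean of 11.1 CPM against 2 counts in the WT pair, a ratio of 373 (95% exact counting interval 103 to 3082). OsMADS14 (Os03g0752800) rose from 7.04 ± 0.0434 to 594 ± 55.3 CPM (SD, n = 2), by 6.38 on the log2 scale (SE 0.08). The NAC factor gene ONAC028 rose by 6.97, the metallothionein gene OsMT1b by 6.49, OsEnS-107 by 6.48, the vacuolar iron transporter gene OsVIT2 by 5.37, SGR by 5.21 and the polyamine-synthesis gene OsACL5 by 5.01. The falls included RBBI2-1, with 1 count in the OE pair and a ratio of 1216 in favour of WT (95% exact counting interval 218 to 48065). OsPEAMT2, which acts in phosphocholine synthesis, fell from 1418 ± 12.1 to 18.3 ± 0.216 CPM (SD, n = 2), a log2 change of -6.30 (SE 0.04). The BURP-domain genes OsBURP02 and OsBURP07 of chromosome 5 changed by -7.76 and -6.31, the glutaredoxin gene OsGRX29 by -7.40, RNS4 by -6.77, the chloroplast protease gene OsFtsH6 by -6.41 and the carbonic anhydrase gene OsalphaCA7 by -6.37. All 8 rises passed against the other WT pair in the same direction, although OsMADS14 and SGR shrank to 0.66 and 0.64 and only OsACL5 grew, to 5.63. OsMADS15 shrank to 2.66 on the log2 scale, and ONAC028, OsMT1b, OsEnS-107 and OsVIT2 to 3.20, 3.07, 3.01 and 4.27. The WT pairs themselves differed by -5.71 for OsMADS15, so its large ratio rests mostly on its low level in the PIP2-7 WT. Of the 8 falls 6 passed in the same direction there, while OsBURP02 (0.036) and OsalphaCA7 (1.61) did not pass. OsGRX29 shrank to -3.36, OsFtsH6 to -3.93, OsBURP07 to -1.83, OsPEAMT2 to -0.72 and RNS4 to -0.29, and RBBI2-1 was lower there too. OsMADS14 and SGR (1.63 and 1.59) and OsBURP02, RNS4 and OsalphaCA7 (-6.75, -5.77 and -5.35) did not pass with all 4 WT libraries as the reference.

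The flowering list rose in the PIP2-7 OE, with 6 members up and 3 down of 11 (the same adjusted over the list alone), and camera gave adjusted p = 1.9e-06, but adjusted p = 0.26 with an estimated correlation. Besides OsMADS15 and OsMADS14, OsMADS18 rose by 2.38 and OsMADS51 by 0.91, and these stood 0.91 and 0.71 above the other WT pair. Other aquaporins had 6 members up and 6 down of 13 (the same adjusted over the list alone) and were lower by camera, with adjusted p = 0.0029, but adjusted p = 0.26 with an estimated correlation. OsTIP1-2, OsTIP4-2, OsTIP2-2 and OsNIP3-1 changed by -3.54, -2.97, -2.26 and -1.53, and OsNIP3-1 turned against the other WT pair (0.43). Of 10 PIP genes 3 rose and 6 fell (the same adjusted over the list alone): OsPIP2-5 and OsPIP2-4 rose by 2.08 and 0.60 beside the target, and OsPIP2-2, OsPIP1-1, OsPIP2-3, OsPIP2-1, OsPIP1-2 and OsPIP2-6 changed by -1.82, -1.13, -0.71, -0.29, -0.23 and -0.20. Against the other WT pair OsPIP2-2, OsPIP2-3 and OsPIP1-1 stood at -0.91, -0.68 and -0.12, while OsPIP2-4, OsPIP1-2 and OsPIP2-6 turned, to -0.64, 0.21 and 0.36, and OsPIP2-5 did not pass (0.23). Clock genes split 4 up and 4 down of 8 (the same adjusted over the list alone), with OsPRR95, OsPRR59 and OsPRR1 up by 1.24, 0.71 and 0.64 and OsLHY at -0.48. Among floral markers 3 rose and 0 fell of 5 (the same adjusted over the list alone), namely OsMADS1 by 2.47, OsMADS16 by 1.51 and OsMADS2 by 0.36, the call of OsMADS2 being lost without WT replicate 2 (0.34) or OE replicate 2 (0.19), or with DESeq2 (0.36). OsMADS1 and OsMADS2 did not pass against the other WT pair (0.16 and 0.29). The secondary wall cellulose synthase genes OsCESA9, OsCESA7 and OsCESA4 rose (3 of 3, the same adjusted over the list alone) at levels of 0.372, 0.478 and 1.30 CPM, OsCESA9 having 3 counts in the WT pair and a ratio of 8.32 (95% exact counting interval 2.56 to 42.9). These calls were lost without WT replicate 1 (edgeR, adjusted p = 0.0619 for OsCESA9, and log2 1.21 and 0.88 for OsCESA7 and OsCESA4), that of OsCESA7 without OE replicate 2 (1.03) and with DESeq2 (1.67), and that of OsCESA4 without any 1 of the 4 libraries compared (0.60 to 0.88), with DESeq2 (0.75) and with no low-count filter (0.73). OsCESA9 and OsCESA7 did not pass against the other WT pair (-0.098 and 0.38). PIP, clock, floral and cellulose synthase lists did not pass camera (lowest adjusted p = 0.24).

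In the PIP2-7 KO line 14968 of 23627 genes differed from WT, 7578 higher and 7390 lower, and 4765 by at least 2-fold (edgeR quasi-likelihood test). The terpene synthase gene OsTPS29 (Os08g0139700, chromosome 8, 2210027 to 2213892) rose from 0.253 ± 0.0505 to 2158 ± 52.3 CPM (SD, n = 2), by 13.03 on the log2 scale (SE 0.07). The resistance-gene homologue rNBS17 and another terpene synthase gene, TPS (Os08g0167800), stood at 21.0 ± 0.53 and 10.3 ± 0.55 CPM (SD, n = 2) and at 0 in both WT libraries, at least 469-fold and 230-fold higher by a floor of 3 counts over the WT pair. OsFKBP73, an immunophilin gene, rose by 10.05 (SE 0.11) and MRKc by 9.10 (SE 0.19). RPBF, OsFbox017 and PIC22 had 1, 1 and 3 counts in the WT pair, with ratios of 1738 (95% exact counting interval 312 to 68703), 950.2 (170.1 to 37568) and 775 (265 to 3759). Among the falls OsFtsH6 had 1 count in the KO pair, with a ratio of 821 in favour of WT (147 to 32467), Awn3-1 and OsFbox011 changed by -8.04 and -7.56, RNS4 by -7.47, the senescence-associated gene OsSAG13 by -6.34, qCTR12 by -6.27, RBBI2-1 by -5.85 and OsalphaCA7 by -5.78. With thresholds chosen after seeing the data, 40 genes were on or off in the PIP2-7 KO libraries alone, 27 of them on, rNBS17, TPS and OsFbox017 included, and 13 off, Awn3-1 included. OsFKBP73 and PIC22 lie within runs of such genes on chromosomes 1 and 4. Of the 8 rises 7 passed in the same direction against the other WT pair, RPBF being lower there (-0.32), and of the 8 falls 7 did so, OsalphaCA7 being higher there (2.18). OsSAG13, Awn3-1 and OsFbox011 kept their size there, at -6.47, -7.85 and -7.39. The fall of qCTR12 was somewhat smaller there, at -5.40, and OsFtsH6 was lower there too. RNS4 and RBBI2-1 shrank there to -1.004 and -1.297. For RNS4 and RBBI2-1 the PIP2-7 WT itself stood at 6.46 and 4.55 relative to the PIP2-1 WT. With all 4 WT libraries as the reference RPBF (0.69), RNS4, RBBI2-1 and OsalphaCA7 (-6.48, -4.91 and -4.78) did not pass.

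The PIP list was lower in the PIP2-7 KO, with 3 members up and 4 down of 10 (the same adjusted over the list alone), and camera gave adjusted p = 0.0197, but adjusted p = 0.56 with an estimated correlation. The list contains the knocked-out gene. OsPIP1-1, OsPIP2-2 and OsPIP2-6 changed by -1.07, -0.93 and -0.64, OsPIP2-5 and OsPIP1-3 rose by 1.18 and 0.74, and OsPIP2-1 rose by 0.10, a call lost without WT replicate 1 (0.077) or KO replicate 2 (0.092). OsPIP1-1 stood at -0.077 against the other WT pair, OsPIP2-5 turned (-0.68), and OsPIP2-2 and OsPIP2-6 did not pass (-0.036 and -0.098). Other aquaporins had 4 up and 6 down of 13, with OsTIP4-2, OsTIP2-2 and OsTIP1-2 at -2.18, -1.58 and -1.48 and OsTIP1-1 at 0.48, and OsTIP2-2 turned against the other WT pair (0.26). Clock genes had 4 up and 4 down of 8, with OsLHY, OsELF3, OsPRR37 and OsPRR73 at -1.03, -0.46, -0.42 and -0.41. Flowering genes had 2 up and 7 down of 11, with OsMADS51 and OsMADS50 up by 0.67 and 0.64 and OsHd1 and OsMADS18 at -1.09 and -0.37, OsHd1 not passing against the other WT pair (-0.31). Floral markers had 1 up and 1 down of 5 (median -0.22 where camera pointed up), and all 4 of these lists had the same counts adjusted over the list alone. Secondary wall cellulose synthases had 1 up and 0 down of 3, and 0 adjusted over the list alone. These 5 lists did not pass camera, other aquaporins coming closest with adjusted p = 0.0504.

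The OE and KO lines of OsPIP2-7 differed from each other in 13713 genes, 6710 higher in OE and 7003 higher in KO (edgeR quasi-likelihood test). Against WT, 4909 genes were higher and 5284 lower in both lines, and 659 were higher in OE and lower in KO and 854 the other way. Independent lists of these sizes would share 2530 and 2492 genes in the same direction and 2468 and 2556 in opposite ones. Simulated unchanged lines against the same WT pair gave a correlation of 0.51 and a covariance of 0.0208, against an observed correlation of 0.499 and covariance of 0.855. The simulated lines, with 0.2 and 0.5 genes called on average, left no room for an overlap. These simulations too held only the spread between libraries of a group, so part or all of the excess may come from the shared WT. OsZFP1 stood at 2.17 in OE and -2.14 in KO, with nearly the same values against the other WT pair (2.22 and -2.12). The metallothionein gene OsMT2b stood at 1.42 and -1.57, the malate transporter gene OsALMT4 at 1.77 and -2.29, and OsSTA246 at 1.84 and -1.86, the rise of OsSTA246 not passing against the other WT pair (0.015). The transcription factor genes OsWRKY104 and OsWRKY95 were lower in OE (-2.70 and -2.68) and higher in KO (5.30 and 4.43), as was the pathogenesis-related gene RSOsPR10 (-2.73 and 2.48). MRKc passed in both directions too, although its 5 counts in the WT pair against 0 in OE allow no fold, and its fall was lost without WT replicate 1 (edgeR, adjusted p = 0.0599), OE replicate 1 (edgeR, adjusted p = 0.0600) or OE replicate 2 (edgeR, adjusted p = 0.0675).

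The experiments were last set side by side. Genes called in both OE lines moved mostly in opposite directions relative to their own WT: 773 were higher and 844 lower in both, while 3599 were higher with OsPIP2-1 and lower with OsPIP2-7 and 2994 the reverse. Independent lists would share 1772, 1662, 1847 and 1594 genes, and Fisher's exact test across genes, which are not independent, gave odds ratios of 0.27, 0.33, 6.37 and 4.87. For the KO lines 805 were higher and 1151 lower in both, while 4202 and 4332 moved in opposite directions, with odds ratios of 0.19, 0.28, 6.17 and 6.12. The correlation of log2 changes across genes was -0.17 for OE and -0.43 for KO. The WT pairs themselves differed in 13907 genes, which can give opposite directions in the experiments. The lines also lay further apart than the WT pairs. The SD of log2 differences was 1.27 between the KO lines and 1.04 between the OE lines, against 0.906 between the WT pairs. These overlaps were not counted against a common WT, so they do not show opposite effects of the target genes. Requiring a call in the same direction against both WT pairs, a rule chosen after seeing the data, left 3810, 6798, 8364 and 7080 genes for PIP2-1 OE, PIP2-1 KO, PIP2-7 OE and PIP2-7 KO. The authors' deposited tables listed 5245, 9876, 10201 and 9318 significant genes for these comparisons. Of these, 4813, 8097, 9214 and 8584 genes in the authors' deposited tables were also called by edgeR, and 4811, 8058, 9176 and 8555 of them had the same sign. Of all genes significant in the authors' deposited tables, 2187 were higher and 3058 lower for PIP2-1 OE, 2746 and 7130 for PIP2-1 KO, 7097 and 3104 for PIP2-7 OE, and 6310 and 3008 for PIP2-7 KO, less even than the edgeR counts above.

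**Figure D2:**
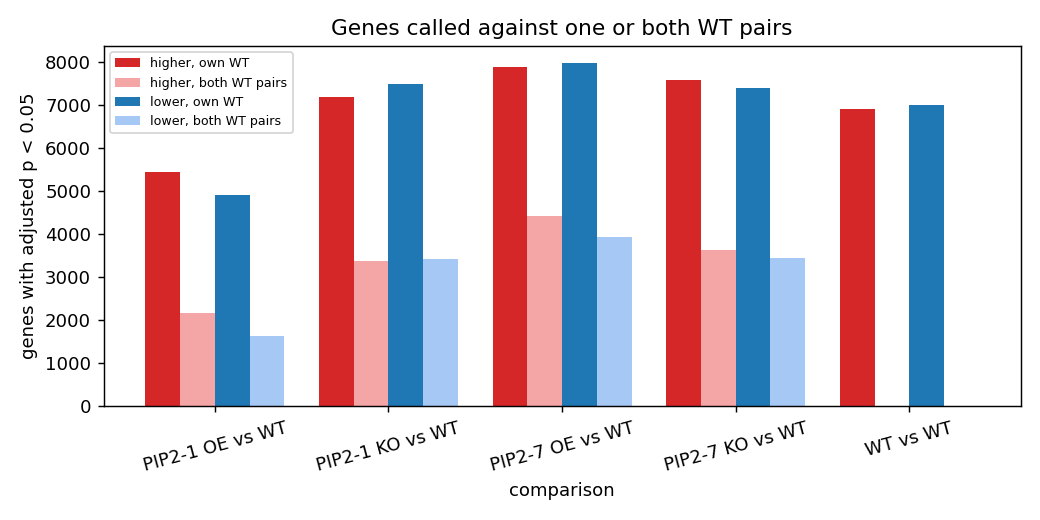
Number of genes with an edgeR adjusted p under 0.05, higher (red) and lower (blue), in each line against its own WT pair (dark) and in the same direction against both WT pairs (light). The WT pairs compared with each other, at the right, differ in 6901 and 7006 genes, and the count against both pairs has no meaning there.

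**Figure D3:**
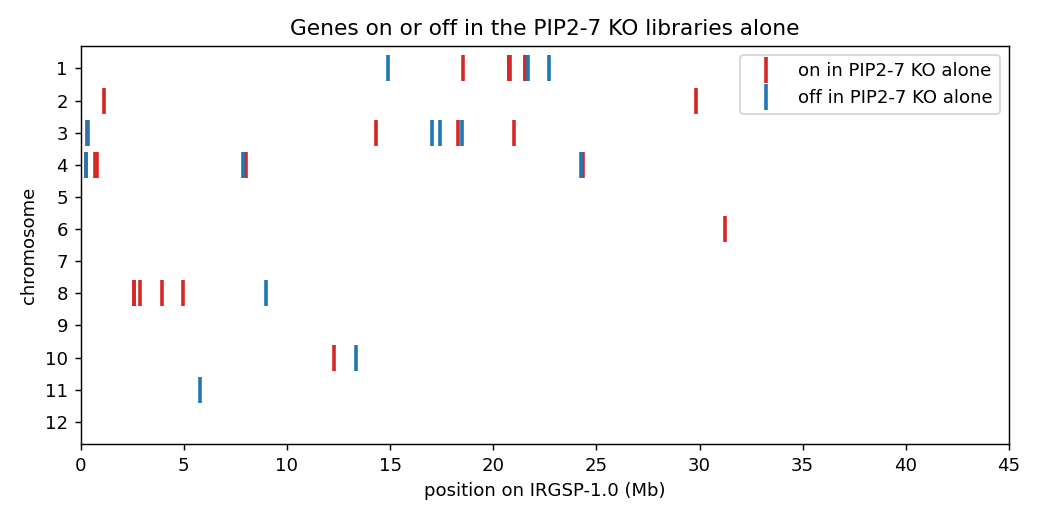
Position on the IRGSP-1.0 chromosomes, in Mb, of the 40 genes found on (red, 27 genes) or off (blue, 13 genes) in the PIP2-7 KO libraries alone, with on meaning at least 3 CPM and off at most 0.15 CPM. Runs of such genes lie on chromosomes 1, 3, 4 and 8.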

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

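The tests weighing explanations of the WT pairs, of shared reads and of chance positions were chosen only after the result was seen, while the test of spread inside chromosome segments was written before its result.

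The effect of overexpression differed between the experiments in 15362 of 24556 genes, and the effect of the knockout in 16533, by the edgeR test of the difference itself. These differences rest on a different WT pair in each experiment, and so include the difference between the WT pairs. As log2 difference of the OE effect, PIP2-1 less PIP2-7, OsPIP2-3 stood at 4.34, OsPIP2-1 at 4.11, OsPIP2-2 at 2.77, OsPIP1-1 at 1.60, OsPIP1-2 at 0.71, OsPIP2-7 at -1.51 and OsPIP2-5 at -3.10. As log2 difference of the KO effect, OsPIP2-7 stood at 3.63, OsPIP2-2 at 2.03, OsPIP1-1 at 2.02, OsPIP2-6 at 1.2499, OsPIP1-2 at 0.68, OsPIP2-4 at -1.49, OsPIP1-3 at -3.26 and OsPIP2-5 at -3.37. The flowering list had a median difference of -1.22 between the OE effects (camera, adjusted p = 6.6e-07, and adjusted p = 0.015 with an estimated correlation).

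The WT pairs differed in 13907 genes. A wrong scaling factor would shift all genes of a library alike, but under the common log2 shift, of those from -3 to 3, that left fewest, 2264 genes were still over 2-fold apart by more than 2 SE, so scaling is argued against as the whole source. A harvest at another time of day would be looked for first in clock genes. The median absolute difference of the clock list lay at the 13.6th percentile of 10000 lists matched on expression. Flowering lay at 99.8 and the chlorophyll breakdown and senescence list at 99.9. Since many genes of the matched lists also differed between the WT pairs, this ranking cannot exclude a smaller shift in time of day. An exchange of the WT pairs between the experiments cannot be told apart from other causes: 3 of the 4 transgenic groups lay nearer the other experiment's WT, with PIP2-1 OE nearer its own (SD of log2 differences 0.77 against 0.876). The labels give the same age for all plants. The day and batch of each WT pair, and any biological difference between them, stay open and untested.

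In the PIP2-7 KO libraries alone, 40 genes were on or off: 27 had at least 3 CPM there and at most 0.15 CPM in the other 10 libraries, and 13 the reverse, against 0 to 4 such genes in any other group. The 40 genes held 20 neighbouring pairs under 1 Mb apart, where 10000 random draws of single genes gave a mean of 4.63 and at most 13. The draws did not match tandem gene families or overlapping loci such as Os01g0564300 and Os01g0564400. The excess therefore argues against independent random positions, but does not exclude local clusters of related genes. Other genes inside the 8 segments so formed (4.55 Mb on chromosomes 1, 3, 4 and 8) differed from the other libraries with an SD ratio of 1.58 to genes outside, against 1.09 to 1.23 in the other groups. Segments were drawn only around extreme genes of this KO, so the other groups are no matched reference. By the median absolute deviation, which outlying genes sway less, the ratio was 1.33, against 0.84 to 1.07. A candidate explanation is therefore segments of another haplotype in that line, such as seed of mixed descent, as a hypothesis found on the same data. Of the largest rises in this line rNBS17, TPS, OsFbox017, OsFKBP73 and PIC22 lie in these segments, and of the largest falls Awn3-1 does. No sequence was examined, and an effect of the edited gene on genes in the segments was not tested.

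OsPIP2-3 rose with OsPIP2-1 in the PIP2-1 OE libraries. Its counts there were 4.34% and 4.59% of those of OsPIP2-1, inside the range of 3.55% to 7.08% in the other 10 libraries, which is consistent with reads shared between the genes. Expression of OsPIP2-3 that follows OsPIP2-1 would give a like value, and stays open.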

How the results depend on the processing

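The tests against both WT pairs, with summed replicates and outside the PIP2-7 KO segments were chosen only after the result was seen. RLE scaling, no low-count filter, DESeq2, the wider and narrower fits, nuclear genes only and each library left out in turn kept every count of called genes within 1.5 times its value, as did leaving out the PIP2-7 KO segments (14780). With all 4 WT libraries as the reference the counts were 2061, 5662, 7363 and 5518 for PIP2-1 OE, PIP2-1 KO, PIP2-7 OE and PIP2-7 KO, and against both WT pairs 3810, 6798, 8364 and 7080, since the WT pairs differ from each other. With replicates summed, so that only the 2 WT sums gave a spread (1 residual degree of freedom), edgeR called 0 genes in each of the 4, with 526, 1207, 1234 and 1136 at an unadjusted p under 0.05. No other tool was run on the sums. OsPIP2-1 then stood at log2 3.81 in its OE line, and OsPIP2-7 at 1.72 in its OE line and at -1.70 in its KO. OsPIP2-1 in its KO ranged from 0.027 to 0.096 with each library left out, where a lone library is assumed to vary like the other groups. Genes called in opposite directions in PIP2-1 OE and KO ranged from 784 to 1252 with each library left out, and the cause was not tested. With all 4 WT as the reference, values reversed for OsPIP1-1 in PIP2-1 OE (-0.091), RNS4 in PIP2-1 KO (-0.42), OsPIP2-4 and OsPIP2-6 in PIP2-7 OE (-0.15 and 0.069) and OsPIP2-5 in PIP2-7 KO (-0.017). Besides those of the largest changes given with the results, that reference ended the calls of OsPIP1-2, OsPIP1-3, OsPIP2-2, OsPIP2-5, OsPIP2-6, OsPIP2-7, OsTIP2-2, OsTIP4-2, OsGI, OsPRR95, OsPRR59, OsPRR73, OsRFT1, OsMADS18, OsMADS51, OsMADS15 and PI21 in PIP2-1 OE. In PIP2-1 KO it ended those of OsPIP1-1, OsPIP1-2, OsPIP2-2, OsPIP2-3, OsPIP2-4, OsPIP2-5, OsPIP2-6, OsTIP2-2, OsTIP4-2, OsLHY, OsMADS14, OsHd3a, OsMADS15, RbohF and GH2. In PIP2-7 OE these were OsPIP1-1, OsPIP1-2, OsPIP2-5, OsTIP2-2, OsNIP3-1, OsMADS1, OsMADS2, OsCESA9, OsCESA7, OsSTA246 and OsALMT4, and in PIP2-7 KO OsPIP2-1, OsPIP1-1, OsPIP2-2, OsPIP2-6, OsTIP2-2, OsPRR37, OsELF3, OsMADS18 and OsHd1. Of the values of named genes under the alternatives, 2368 kept direction and side of the threshold and 104 lost the threshold. The number of fixed lists past the threshold, 1, 0, 2 and 1 in the 4 comparisons, became 0 in each with an estimated correlation, and 3, 5, 6 and 3 with fry, which asks another question. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated across genes at -0.024 to 0.0243. With the replicate block the counts were 10100, 14472, 15753 and 14916, the WT pairs differed in 12400 genes, and 0 fixed lists passed in PIP2-7 OE and PIP2-7 KO. DESeq2 ended the calls of OsPIP2-6 in PIP2-1 OE, OsPIP2-3 in PIP2-1 KO and OsMADS2, OsCESA7 and OsCESA4 in PIP2-7 OE. Some calls depended on single libraries, both of genes of few counts (OsCESA4, OsCESA7, MRKc) and of genes of more counts (OsPIP1-3 and OsPIP2-6 in PIP2-1 OE, OsPIP2-1 in PIP2-7 KO).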

Other observations

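All tests in this part were chosen only after the result was seen, on lists defined from gene names.

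Of 31 tested genes of the photosynthetic light reactions, 21 rose and 4 fell in PIP2-1 OE, 28 rose and 2 fell in PIP2-1 KO, 4 rose and 25 fell in PIP2-7 OE, and 3 rose and 25 fell in PIP2-7 KO. The list passed camera in all 4 comparisons but in none with an estimated correlation (lowest adjusted p = 0.19). PsbO rose by 1.04 and 2.09 and then changed by -2.09 and -2.07 in these comparisons, and the light-harvesting gene LHCB (Os03g0592500) by 1.15, 1.74, -2.56 and -1.94. Chlorophyll breakdown and senescence genes had 4 up and 10 down of 23 in PIP2-1 OE, 3 up and 13 down of 23 in PIP2-1 KO, 19 up and 2 down of 24 in PIP2-7 OE and 14 up and 5 down of 24 in PIP2-7 KO. NYC3 changed by -1.21, -1.70, 1.72 and 1.93 and OsRCCR1 by -1.82, -2.17, 2.29 and 2.64. This list too passed camera in all 4 comparisons, but with an estimated correlation the lowest adjusted p of any added list in any of the 4 was 0.19. Between the WT pairs the same lists differed, with 26 photosynthesis genes higher and 3 lower in the PIP2-7 WT (camera, adjusted p = 0.036 with an estimated correlation) and 13 senescence genes lower and 4 higher (camera, adjusted p = 0.036 with an estimated correlation). That fit held 12 libraries, against 6 in each of the 4 comparisons, so a list could pass more readily there. These p-values do not show that the lists changed less in the lines. Against both WT pairs, 3, 20, 4 and 2 photosynthesis genes were higher and 3, 0, 13 and 12 lower in the 4 comparisons, and 3, 2, 10 and 6 senescence genes were higher and 2, 5, 0 and 4 lower.

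Ribosomal protein genes had 59 of 76 up and 0 down in PIP2-1 OE, 68 up and 3 down in PIP2-1 KO and 2 up and 67 down in PIP2-7 OE, but 20 up and 31 down in PIP2-7 KO. Between the WT pairs 73 were higher and 1 lower (camera, adjusted p = 0.045 with an estimated correlation), and against both WT pairs 0, 9, 2 and 20 were higher and 0, 3, 5 and 1 lower. WRKY transcription factor genes fell in PIP2-1 KO (6 up and 50 down of 68; camera, adjusted p = 6.2e-08, but adjusted p = 0.19 with an estimated correlation) and rose in PIP2-7 KO (39 up and 11 down of 70; camera, adjusted p = 2.0e-05, but adjusted p = 0.19 with an estimated correlation). Against both WT pairs 2 were higher and 24 lower in PIP2-1 KO, and 18 higher and 6 lower in PIP2-7 KO. Of the 20 lists, 7, 12, 7 and 8 passed camera in PIP2-1 OE, PIP2-1 KO, PIP2-7 OE and PIP2-7 KO, and 0 did with an estimated correlation.

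A set of 12 genes was on in both OE lines (at least 3 CPM in each of their libraries) and at most 0.15 CPM in every WT and KO library, with the thresholds chosen after seeing the data. None had a name. Os10g0460800 stood at 7.94 ± 0.183 CPM in PIP2-1 OE and 19.8 ± 0.186 CPM in PIP2-7 OE (SD, n = 2), and Os06g0190900 at 6.97 ± 0.187 and 16.1 ± 0.706 CPM (SD, n = 2), with 0 counts in the 8 other libraries. Os01g0379800, Os12g0537000 and Os10g0549900, on different chromosomes, stood at 6.28, 6.05 and 6.03 CPM in PIP2-1 OE and at 8.79, 9.16 and 9.13 CPM in PIP2-7 OE. Reads with several alignments were counted at each place, and per the labels the KO lines hold no T-DNA. Shared sequence with the T-DNA was not examined, so these counts do not show that the reads came from these loci.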
